A study of Mus musculus with 28 samples.

How the data were processed

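The series holds 28 samples of NIH/3T3 Tet-On 3G cells, an immortalised mouse embryonic fibroblast line that carries a doxycycline-dependent transactivator. Chromatin immunoprecipitation with sequencing (ChIP-seq) of unmodified cells covered 6 subunits of the NuRD complex (nucleosome remodelling and deacetylase), namely CHD4, HDAC1, HDAC2, MBD2/3, MTA1 and RBBP4, and 3 histone modifications, H3K27ac, H3K4me3 and H3K9ac, with 1 library each. A tagged copy of the histone variant H3.3 was precipitated through its HA tag in 2 replicates from cells arrested with aphidicolin and given doxycycline. In a sequential ChIP, chromatin was taken first with a FLAG antibody, which binds the tagged H3.3, and then with an RBBP4 antibody or with IgG. MTA1 and RBBP4 were also precipitated from cells transduced with constructs named for luciferase (control) and from cells transduced with constructs named for H3.3A and H3.3B (H3.3 knockdown), with 1 library per protein and condition. Polyadenylated RNA was sequenced from 2 control clones and 3 knockdown clones. Every sample was assigned to its group from the labels alone. Inputs accompany each ChIP set and were not used here, because no file used here carries their values.

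Per the submitters' processing notes, Bowtie, bedtools, TopHat, Cufflinks, Cuffdiff and MACS2 were used with the mouse genome build mm9. The notes as used here give no version and no role for each tool, and duplicate handling and input subtraction for most files are not given in the sources used here. All coordinates are mm9, printed 1-based.

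The RNA files hold FPKM per gene as deposited, in 1 table per library with the columns that Cufflinks writes, per the file headers. Each table had 24457 entries for 23951 gene symbols, and the entries of a symbol were summed. Because the tables hold no read counts, fragments per gene were estimated from the upper confidence bound of each FPKM, taken as 2 SD of a Poisson count. Summed over genes they came to 25.9 and 25.2 M for control clones 1 and 2, and to 18.2, 26.5 and 18.6 M for knockdown clones 1 to 3. Only 54.6% to 57.5% of these estimates under 20 were whole numbers within 0.05, so they are approximate and were used to judge depth and for 1 added filter, never in a count test. A gene with 1 or 2 estimated fragments can have a large FPKM when its transcript is very short, which matters for microRNA and small nucleolar RNA genes. Between 11289 and 11608 symbols per library had an FPKM of at least 1. Strand was not stated, so overlapping and antisense genes cannot be separated, and genes with processed pseudogenes, such as H3f3a, H3f3b, the ribosomal protein genes and the clustered histone genes, may share reads with their copies.

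The deposited table of levels lists 82893 regions with a median length of 840 bp, per the file headers as RPKM; the deposited values are on a log2 scale, log2(RPKM + 1). Read that way, 100% of values under 100 reads came out as whole reads within 0.05 in every library, against 7.55% to 10.0% if they were read as plain RPKM. The reads recovered this way numbered 13.6 and 18.4 M for the HA-H3.3 replicates, 9.17 M for CHD4, 8.68 M for HDAC1, 6.62 M for HDAC2, 7.96 M for MBD2/3, 11.0 M for MTA1, 9.00 M for RBBP4, 20.6 M for H3K27ac, 24.1 M for H3K4me3 and 22.0 M for H3K9ac. The median region held 7 to 46 reads, which gives a counting error (CV) of 37.8% to 14.7%. A second deposited table gives, for the same regions, the fraction of each region covered by the peaks of each of the 8 H3.3 and subunit libraries, as values from 0 to 1. Every region holds a peak in at least 1 of those libraries, so a region without a subunit peak has an H3.3 peak in at least 1 replicate by construction. That table also counts annotated gene features per region, and regions with a feature in the 3 kb upstream class or the 5'UTR class are called annotated promoters here. Neither table as used here holds an input column.

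The peak lists were deposited with 1 list per library and a score per peak. The lowest deposited score of about 50 and the peak names match the score that MACS writes, −10 times the log10 of the peak p-value, and the scores were used to rank and filter peaks within a list. The MTA1 lists held 1703 control and 904 knockdown peaks with median widths of 150 and 861.5 bp. The RBBP4 lists held 3561 and 2919 peaks with median widths of 221 and 191 bp. H3K27ac had 26629 peaks, H3K4me3 32099 and H3K9ac 16493. The depth of the control and knockdown ChIP libraries is unknown. The sequential ChIP list was called with MACS 2.1.1.20160309 at a q-value limit of 0.05 from 20.4 M treatment and 4.92 M control tags, per the file headers. It gives pileup signal, −log10 p and −log10 q, and fold enrichment, each as deposited by the authors. The fold enrichment, a ratio, was used as deposited.

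Knockdown and control clones were compared with limma (lmFit, eBayes with trend, two-sided) on log2(FPKM + 1) over the 11728 genes with a mean FPKM of at least 1, with Benjamini-Hochberg adjustment at 0.05. Changes are on the log2(FPKM + 1) scale, which understates those of low genes. The p-values of the RNA comparison measure the spread between clones. Tested on simulated data for this comparison, with 200 of the 11728 genes changed, the fit recovered 6% of 50 genes shifted by a log2 value of 1, 72% at 2, 94% at 3 and 100% at 4, with 12 false among 148 calls. The changed genes were drawn from the more highly expressed ones, with normal noise, so recovery of low genes was not tested. Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the residuals. In a simulated test of the list comparison, a list of 20 genes shifted by 1 passed the threshold, and 3 of 100 unshifted lists had an unadjusted p under 0.05. The simulated genes were independent, while the estimated correlation was 0.911 for the cell cycle list and 0.889 for the sterol list. That test thus gives no false call rate for correlated lists. The 27 lists, the tests, the named-gene rule and most alternatives were fixed before the data were examined; 21 lists had the 5 measured members needed for a test. The lists cover NuRD subunits, H3.3 deposition factors, replication-coupled histone genes, cell cycle, p53, interferon, inflammation, matrix, contractile genes, proteases, immediate early genes, sterol synthesis, stress response, glycolysis, Hox, imprinted and ribosomal protein genes, axon guidance, Wnt and BMP targets, and markers of fibroblasts and 7 other cell types.

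Peak lists were compared by overlap of at least 1 bp, with exact (Clopper-Pearson) 95% intervals; intervals cover counting error only. The overlap code was tested on simulated data and gave the known answer for 300 of 300 intervals under each of its rules. With 1 library per condition no test between conditions was made. Random placements of each list (1000, same lengths, same chromosome) gave the background for overlap with histone marks. A gene was given a peak when the peak lay within 2 kb of either end of its locus, since the loci in the RNA tables carry no strand. A level per gene was the length-weighted mean RPKM of the regions in those windows, then log2(RPKM + 1). Correlations across regions or genes are Spearman's rho. The nearest gene of a peak is the one with the nearest locus end, with short RNA genes and unnamed transcripts skipped.

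Genes were named by rule: H3f3a, H3f3b and each NuRD subunit gene; in each direction the genes past the test with every knockdown clone beyond both controls, filled up to 10 by the smallest p and then given as values only; and from each list up to 4 members past the test or else the 2 of highest mean FPKM. A few genes that this rule names are not reported here. For peaks, the 5 highest in control, lost and only in knockdown were named, with all sequential ChIP peaks and the 3 highest regions per library. Several plans had to change. No input or fold column was at hand, so levels were not divided by input and peaks were ranked by score; the stricter list used a score of at least 100, that is −log10 p of at least 10. The planned gene-level table held regions, and promoters had to be both gene ends. The alternatives tried were other pseudocounts, filters and scalings, a replicate block, array weights, leaving out each library, other overlap rules, windows and thresholds, and, chosen after the data were seen, leaving out short RNA genes, a minimum of 10 estimated fragments, 4 length classes of regions and gene ends with an H3K4me3 peak. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.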

Results

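H3.3 is a histone H3 variant that is laid down outside of DNA replication, in mice from the genes H3f3a and H3f3b, and NuRD is a complex that couples nucleosome remodelling to histone deacetylation. The samples address where NuRD subunits and H3.3 lie in mouse fibroblasts, and what H3.3 depletion does to the binding of the subunits MTA1 and RBBP4 and to gene expression. Expression was measured in 2 control and 3 knockdown clones, at an estimated 18.2 to 26.5 M fragments per library. Binding of MTA1 and RBBP4 was measured in 1 control and 1 knockdown library each. Subunits and histone modifications in unmodified cells had 1 library each, and HA-tagged H3.3 had 2 replicates.

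Both H3.3 genes were lower in each of the 3 knockdown clones than in both control clones. H3f3a had an FPKM of 128.3 and 143.5 in the controls and of 71.8, 35.6 and 5.05 in knockdown clones 1 to 3, that is 52.8%, 26.2% and 3.71% of the control mean. H3f3b had an FPKM of 249.4 and 237.1 in the controls and of 144.4, 104.3 and 51.7 in the knockdown clones, or 59.4%, 42.9% and 21.3% of the control mean. Depletion was thus weakest in clone 1 and strongest in clone 3. Neither gene passed the limma test over all genes: the log2 difference was −2.44 (SE 1.04, adjusted p = 0.516) for H3f3a and −1.39 (SE 0.45, adjusted p = 0.469) for H3f3b. With 1 clone left out it ran from −3.20 to −1.41 for H3f3a and from −1.71 to −0.98 for H3f3b.

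**Figure D1:**
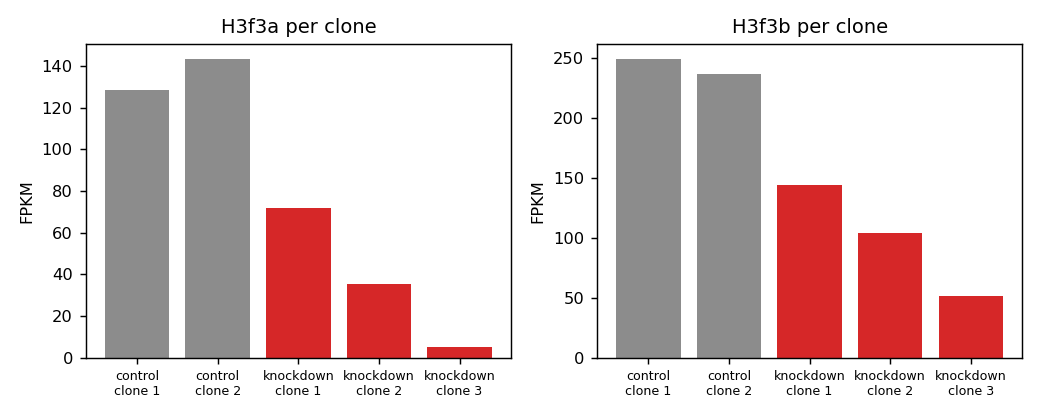
FPKM (y axis, linear from 0) of H3f3a (left) and H3f3b (right) in each control clone (grey bars) and knockdown clone (red bars); each bar is 1 library, with no error bar. All 3 knockdown clones lie below both controls, with 5.05 FPKM of H3f3a in knockdown clone 3 against 128.3 and 143.5 in the controls.

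Of the genes for NuRD subunits, 14 of 15 were expressed above the minimum, and none passed the test; Chd5, a remodeller best known from neurons, was below it. Mbd2, which encodes a reader of methylated CpG, had an FPKM of 15.7 and 21.6 in the controls and of 32.6, 32.0 and 28.9 in the knockdown clones (log2 difference 0.72, SE 0.21, limma adjusted p = 0.457). Gatad2a, a scaffold subunit, had 45.5 and 39.3 against 22.0, 28.3 and 36.4 (log2 difference −0.56, SE 0.26, adjusted p = 0.520). Mta1 itself had 64.3 and 71.1 against 51.9, 60.9 and 33.4 (log2 difference −0.51, SE 0.30, adjusted p = 0.561). The log2 difference was −0.26 for Rbbp4 and −0.25 for Cdk2ap1, −0.18 for Mbd3, −0.17 for Chd4 and for Hdac2, −0.15 for Rbbp7, −0.12 for Mta2 and −0.04 for Gatad2b. It was 0.10 for Hdac1, 0.21 for Mta3 and 0.30 for Chd3. Leaving out 1 clone turned the sign in at least 1 fit for Mbd3, Hdac2, Rbbp7, Mta2, Gatad2b and Hdac1. As a list, the 14 genes had a median of −0.16 and a mean of −0.08 with camera pointing upward (FDR 0.985), and the 11 factors that deposit H3.3, among them Hira, Daxx and Atrx, had a median of −0.15 and a mean of −0.13, with camera again pointing upward (FDR 0.985). In the latter list, the 2 members of highest FPKM were Dek (log2 difference 0.08) and Asf1b (−0.95), a histone chaperone gene of dividing cells.

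At the preset correlation, genes of cell division, of the amino acid and unfolded protein stress response and of sterol synthesis fell as groups in the knockdown clones, and ribosomal protein and contractile genes rose as groups. With an estimated correlation camera in limma called 0 of the 21 lists (smallest adjusted p = 0.806, with 0 lists at an unadjusted p under 0.05), and the direction of the ribosomal list turned under quantile normalization. No single member of the 5 lists passed the test over all genes. Of 27 measured cell cycle and DNA replication genes 26 were lower (median log2 difference −0.82, FDR 0.000990; adjusted p = 0.959 with an estimated correlation). Pcna, the sliding clamp of DNA polymerases, had an FPKM of 266.7 and 152.1 in the controls and of 76.0, 173.3 and 114.6 in the knockdown clones (log2 difference −0.81, limma adjusted p = 0.551), and the difference was −0.55 for the mitotic activator Cdc20. Chosen after their values were seen, the cell cycle transcription factor E2f1 had −0.99 and the replicative helicase subunit Mcm2 −1.43. The median of the list was 0.32 and −0.32 in control clones 1 and 2 relative to their mean, and −1.61, −0.28 and −0.54 in knockdown clones 1 to 3. Knockdown clone 1 also stood apart over all genes, at 72.58 on the first principal component (39.1% of the variance) with the other libraries between −40.09 and 0.59. Without control clone 1 the list lost its call (FDR 0.251), and without knockdown clone 1 it had an FDR of 0.0435. Its mean difference to other genes was −0.69 with all clones, −0.34 without control clone 1, −0.30 without knockdown clone 1 and −1.03 without control clone 2.

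In the integrated stress response list 18 of 19 genes were lower (median −0.76, FDR 0.00286; adjusted p = 0.806 with an estimated correlation), with list medians of −0.78, −0.48 and −0.49 in the knockdown clones. Its transcription factor Atf4 had an FPKM of 341.1 and 364.4 in the controls and of 156.3, 261.8 and 204.3 in the knockdown clones (log2 difference −0.79, limma adjusted p = 0.485), and the chaperone gene Hsp90b1 had a difference of −0.32. Among targets of Atf4, chosen after their values were seen, the difference was −1.43 for Asns (asparagine synthetase) and −1.97 for Trib3. In sterol biosynthesis 18 of 19 genes were lower (median −0.59, FDR 0.0165; adjusted p = 0.959 with an estimated correlation), with −0.45 for Fdps, an enzyme of the pathway. The sterol list had a median of −1.17 in knockdown clone 3 but of 0.12 in clone 2, and it lost its call without control clone 2 (FDR 0.203), knockdown clone 1 (0.0992) or knockdown clone 3 (0.431). Its mean difference to other genes was −0.45 with all clones and −0.35, −0.42 and −0.15 in these 3 settings, and −0.77 without knockdown clone 2. The stress list lost its call without control clone 2 (FDR 0.0773), with a mean difference of −0.50 against −0.60 with all clones.

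Among cytosolic ribosomal protein genes 20 of 31 were higher, by little (median 0.07, mean 0.17, FDR 0.00510; adjusted p = 0.806 with an estimated correlation). The most abundant members went both ways, with a log2 difference of 0.44 for Rplp1 (limma adjusted p = 0.512) and −0.41 for Rps2. After quantile normalization the list had a mean difference to other genes of −0.035 (FDR 0.704), so its direction turned with the scaling. In the contractile and TGF-beta responsive list 11 of 17 genes were higher (median 0.15, mean 0.18, FDR 0.0165; adjusted p = 0.806 with an estimated correlation). The smooth muscle actin gene Acta2 had an FPKM of 293.2 and 163.6 in the controls and of 477.9, 717.8 and 292.7 in the knockdown clones (log2 difference 1.08, limma adjusted p = 0.512), and the tropomyosin gene Tpm1 had a difference of 0.59. Not all members moved this way: Ctgf, a secreted growth factor named after its values were seen, had −2.30. Both lists lost their call without control clone 2, where the FDR was 0.0568 for ribosomal and 0.245 for contractile genes, the latter with a mean difference to other genes of −0.06. The ribosomal call was also lost without knockdown clone 1 (FDR 0.0992), and the contractile call without knockdown clone 2 (FDR 0.0664) and after quantile normalization (FDR 0.0535).

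**Figure D2:**
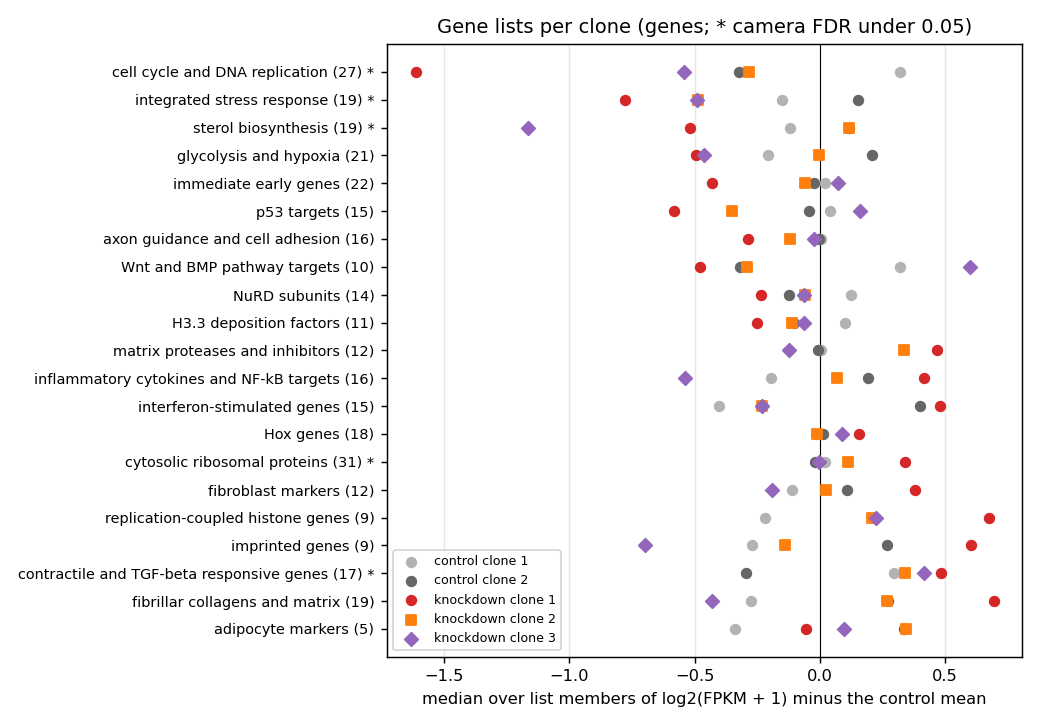
Median over the members of each tested list (y axis, number of measured genes in parentheses) of log2(FPKM + 1) minus the control mean (x axis), with 1 point per clone; a star marks lists past the camera threshold. The cell cycle list has its lowest value, −1.61, in knockdown clone 1, while clone 2 (−0.28) lies within the range of the controls (−0.32 to 0.32).

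The other 16 tested lists had no call. Collagen and matrix genes came closest (11 of 19 higher, median 0.34, mean 0.09, FDR 0.0751), with a log2 difference of 0.93 for Col1a2 (limma adjusted p = 0.447) and 0.10 for Bgn; the list gained a call without control clone 2 (FDR 0.00889) or knockdown clone 3 (FDR 0.00612). The FDR was 0.237 for Hox genes (median 0.03; Hoxd8 −0.95, Hoxa5 0.48), 0.30 for glycolysis and hypoxia genes (median −0.24; Gapdh −0.16, Pkm −0.20) and 0.336 for adipocyte markers (median 0.58; Plin2 −0.10, Scd1 0.66). Glycolysis gained a call without control clone 1 (FDR 0.00484) and after quantile normalization (0.0322), and interferon-stimulated genes gained one without control clone 2 (FDR 0.0371). The FDR was 0.474 for both the replication-coupled histone genes (median 0.09, with Hist2h2aa1 0.31 and Hist1h1c −0.48) and the matrix proteases and inhibitors (median −0.06, mean 0.10, test upward, with Ctsl −1.26 and Timp2 0.69). Only 9 of the 23 replication-coupled histone genes were measured, and only in polyadenylated RNA. Their values thus do not show whether replication-coupled histones changed with H3.3 depletion. Fibroblast markers had an FDR of 0.50 (median 0.08; S100a4 0.95, Vim −0.02) and interferon-stimulated genes one of 0.638 (median 0.00, mean −0.01, test upward; Isg15 0.03, Ifi35 −0.09). For p53 targets (median −0.20; Phlda3 −0.28, Ccng1 −0.51) and for inflammatory genes (median −0.05, mean −0.38, test upward; Il1rl1 −1.55, Csf1 0.16) the FDR was 0.840. It was 0.985 for immediate early genes (median −0.22; Egr1 0.39, Myc −0.25), imprinted genes (median 0.13, mean 0.11, test downward; Gnas −0.43, Dlk1 0.80), axon guidance genes (median −0.17; Cdh2 0.53, Nrp1 −0.18) and Wnt and BMP targets (median −0.17; Id3 1.34, Id1 0.16). Too few members were expressed to test skeletal muscle (4; Acta1 −0.36, Des −0.51), cartilage and bone (3; Spp1 −1.32, Sox9 0.32), haematopoietic (4; Cd14 0.39, Cd74 0.63), epithelial (1; Krt14 0.08), endothelial (3; Egfl7 −0.56, Tek 1.00) and neural markers (0; Mbp stayed at or below 1.35 FPKM).

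No list member passed the test over all genes, and adjusted over the list alone 6 did: the matricellular Thbs2 (log2 difference −2.68), the imprinted Peg3 (−1.44), the repulsive guidance cue Sema3a (−1.09), the endothelial cadherin Cdh5 (−2.27), and the fibroblast genes Twist2 (−1.13) and S100a4 (0.95). This adjustment did not cover the number of lists, and Cdh5 passed in a list of 3 measured genes. In each of these 6 genes all 3 knockdown clones lay on 1 side of both controls, which goes with a small p and is no separate evidence.

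Across all 11728 genes, few single genes passed the test between knockdown and control clones. Only 4 passed limma's test, 1 higher and 3 lower, while 1150 had an unadjusted p under 0.05, of which 410 were higher and 740 lower. The median log2 difference over all genes was −0.098, and −0.006 after quantile normalization. Counts of higher and lower genes, here and in the lists, carry that offset. All 4 genes past the test encode short RNAs and rest on at most 2 estimated fragments per library. The small nucleolar RNA gene Snord73a was listed at 0 in both controls and had an FPKM of 313.4, 216.3 and 308.6 in the knockdown clones (adjusted p = 0.00173). The microRNA genes Mir6948 (231.6 and 464.4 FPKM in the controls, adjusted p = 0.00355), Mir6993 (317.3 and 159.1, adjusted p = 0.00355) and Mir1907 (23.5 and 47.2, adjusted p = 0.0292) were listed at 0 in all knockdown clones. With short RNA genes left out, limma called 0 of 11365 genes, with 1230 at an unadjusted p under 0.05. The count was 36 without control clone 1, 28 without control clone 2, 9 without knockdown clone 1 and 13 without knockdown clone 2, of which 31, 27, 9 and 12 were short RNA genes. Mir1907 lost its call without knockdown clone 1 (adjusted p = 0.0705), 2 (0.111) or 3 (0.153), with a pseudocount of 0.01 (0.183) and with no filter (0.102) or one at an FPKM of 5 (0.157), as did Mir6948 (0.0518) and Mir6993 (0.0576) without knockdown clone 3. In 3823 genes (32.6%) all knockdown clones lay on 1 side of both controls. For a single gene without a change the expected rate is 20.0%. Genes vary together within a clone and no other split of the clones was counted, so the excess cannot be credited to the knockdown.

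Among protein-coding genes, those of smallest p are given as values, since none passed the test. Higher in all 3 knockdown clones were the vacuolar proton pump subunit Atp6v0c (FPKM 58.7 and 47.9 against 256.4, 188.0 and 269.7; log2 difference 2.13, SE 0.24, limma adjusted p = 0.219) and the sialomucin Cd164 (20.9 and 23.0 against 104.7, 92.3 and 71.5; log2 difference 1.96, SE 0.23, adjusted p = 0.219). The lysine methyltransferase gene Setd7 had a log2 difference of 1.45 (SE 0.17, adjusted p = 0.219), the calcium channel gene Cacna1a 1.64, the mitochondrial inner membrane gene Apool 1.16 and Ccdc34 1.80. Lower in all 3 were the engulfment receptor Megf10 (FPKM 4.78 and 4.72 against 0.00491, 0.0102 and 0.0193; log2 difference −2.51, SE 0.22, adjusted p = 0.115), the steroid dehydrogenase Akr1c18 (8.55 and 18.9 against 0, 0.0767 and 0.146; adjusted p = 0.139) and the thrombin receptor Thbd (50.8 and 41.9 against 5.38, 10.1 and 8.79; log2 difference −2.41, SE 0.29, adjusted p = 0.219). The adhesion receptor gene Cd97 had a log2 difference of −2.19 and Lypd1 one of −2.14. Megf10 passed the test without a filter on low values (adjusted p = 0.0178), without the trend (0.0248) and with array weights (0.0255). Akr1c18 passed it without control clone 1 (adjusted p = 0.0185) and with array weights (0.0417), which also called Cd164 and Cd97. The short RNA genes among those of smallest p were Mir8114, Snord72 and Mir7060 on the higher side, and Mir466i and Mir7670 on the lower side, with up to 5.16 estimated fragments in any library.

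The share of MTA1 and RBBP4 control peaks that were found again in the knockdown cells rose with the score of the peak. Of 1703 MTA1 control peaks 275 (16.1%, exact 95% interval 14.4 to 18.0) were overlapped by a knockdown peak, and of 904 knockdown peaks 190 (21.0%, 18.4 to 23.8) were overlapped by a control peak. For RBBP4, 1206 of 3561 control peaks (33.9%, 32.3 to 35.4) and 1378 of 2919 knockdown peaks (47.2%, 45.4 to 49.0) overlapped. When 50% of the peak had to overlap, 15.9% of MTA1 control and 2.21% of MTA1 knockdown peaks did so, and 20.6% of RBBP4 control and 41.9% of RBBP4 knockdown peaks. More of the MTA1 than of the RBBP4 control peaks had a low score: 1020 of 1703 and 1369 of 3561 lay below 60 on the authors' score. By score class, the shares of MTA1 and RBBP4 control peaks overlapped were 5.49% (4.17 to 7.07) and 11.5% (9.90 to 13.4) below 60, and 15.0% (11.6 to 18.9) of 387 and 21.5% (18.7 to 24.6) of 780 at 60 to 80. From a score of 80 the intervals of the 2 factors overlapped widely, with 42.9% (33.2 to 52.9) and 39.5% (34.2 to 44.9) at 80 to 100, 50.4% (41.5 to 59.2) and 57.8% (53.9 to 61.7) at 100 to 200, and 83.3% of 60 (71.5 to 91.7) and 86.0% of 442 (82.4 to 89.1) at 200 or more. Of the 275 MTA1 control peaks found again, 116 had a score of 100 or more. The 2 MTA1 lists differ in form, since control peaks had a median width of 150 bp and covered 342.6 kb while knockdown peaks had one of 861.5 bp and covered 873.1 kb. With 1 library per condition, this difference has no replicate check.

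**Figure D3:**
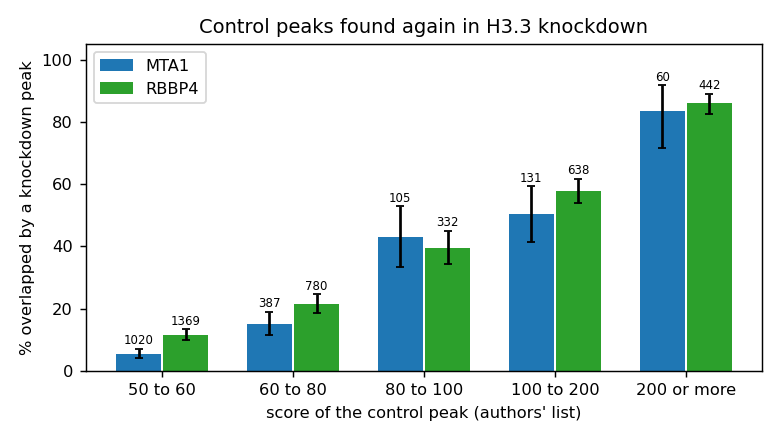
Share of control peaks overlapped by at least 1 bp by a knockdown peak (y axis, percent) in classes of the authors' peak score (x axis) for MTA1 (blue) and RBBP4 (green); error bars are exact 95% binomial intervals and the number of control peaks stands above each bar. The share rises from 5.49% to 83.3% for MTA1 and from 11.5% to 86.0% for RBBP4.

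The strongest MTA1 peaks of the control cells lay outside promoters of protein-coding genes. They were at the 45S ribosomal RNA gene Rn45s (chr17:39979937-39983894, score 3100), at 2 intergenic sites more than 1 Mb from Lrrc4c (chr2:98506379-98507493 and chr2:98502376-98503152), inside Cacng4 (chr11:107645380-107645963) and again at Rn45s (chr17:39984386-39985777). Of the 5 strongest knockdown peaks 4 were at the same places. The Rn45s and intergenic sites also had the highest levels of H3.3 and of every subunit in unmodified cells. Signal that all libraries share there cannot be told apart from MTA1 binding. The strongest MTA1 control peaks without a knockdown peak lay in the axon guidance gene Slit2 (chr5:48377316-48377764, score 346.0), at the end of the RNA editing gene Adarb1 (chr10:76880440-76880989, score 233.5), beside the myelin gene Pmp22 (chr11:62944268-62944871, score 226.3), and at Fam53a and Lrrfip1, all of them in H3K4me3 peaks. Peaks only in the knockdown list were led by Cited2 (chr10:17441849-17443833, score 158.8), a transcriptional co-regulator gene, followed by Tmprss6, Ccdc88a, Sh3rf3 and the kinase gene Pim3, each overlapped by peaks of all 3 histone marks.

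RBBP4 peaks were strongest inside Hivep3 (chr4:119704307-119706717, score 3150.5), at Pmp22 (chr11:62944348-62947240), Rn45s (chr17:39979929-39985787) and Zfp800 (chr6:28210349-28212770), each with a score of 3100, and at Cnnm3 (chr1:36568351-36570416, score 2770.2). The strongest without a knockdown peak lay at Tgif2, a repressor of TGF-beta signalling (chr2:156666155-156667453, score 771.4), at Kctd15 (chr7:35437959-35439283, score 713.7), at Sertad4, at Sirpa and at Ctif. Only in the knockdown list, the strongest was at Sfi1 (chr11:3091042-3094377, score 347.7), outside any of the 3 marks, followed by Arhgap10, the cyclin gene Ccng2, the mitotic kinesin gene Kif14 and the transcription factor gene Ets2. The Sfi1 peak lies in a region (chr11:3090811-3098657) that had a peak of all 6 subunits in unmodified cells, RBBP4 included. Signal that all libraries share there cannot be told apart from a gain of RBBP4. The shares of MTA1 and RBBP4 peaks that overlapped each other were close in control and knockdown cells. RBBP4 peaks overlapped 32.8% of MTA1 peaks in control cells and 32.4% in knockdown cells, and MTA1 peaks overlapped 13.2% and 14.2% of RBBP4 peaks. However, MTA1 peaks had a median width of 150 bp in control and 861.5 bp in knockdown cells, and wider peaks overlap others more readily. These shares were not set against random placement. Whether MTA1 and RBBP4 share sites equally in both conditions thus cannot be told from them.

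RBBP4 peaks lay largely in active promoter chromatin, MTA1 peaks less so. H3K4me3, a mark of active promoters, overlapped 73.7% (72.2 to 75.1) of RBBP4 control peaks, H3K9ac 64.8% and H3K27ac 31.1%, where H3K9ac and H3K27ac are marks of active promoters and enhancers. For MTA1 control peaks the shares were 36.1% (33.8 to 38.4), 28.9% and 12.4%. Random placement of the same lengths gave 2.72% for H3K4me3 at RBBP4 and 2.58% at MTA1, and placement within 5 kb of gene ends gave 12.9% and 12.4%. In the knockdown lists the share with H3K4me3 was 84.5% (83.2 to 85.8) for RBBP4 and 60.1% (56.8 to 63.3) for MTA1. The MTA1 knockdown peaks were wider than the control ones, and placement near gene ends gave 16.2% for them. When 50% of the peak had to overlap, their share was 58.5% for H3K4me3. For H3K27ac it went from 38.1% to 8.19% under that rule, and from 12.4% to 8.28% for MTA1 control peaks. The control peaks that were overlapped in knockdown carried H3K4me3 in 92.8% of cases for RBBP4 and 70.5% for MTA1, and those that were not in 63.9% and 29.5%. The histone marks were measured in unmodified cells, so these shares say nothing about marks in knockdown cells.

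**Figure D4:**
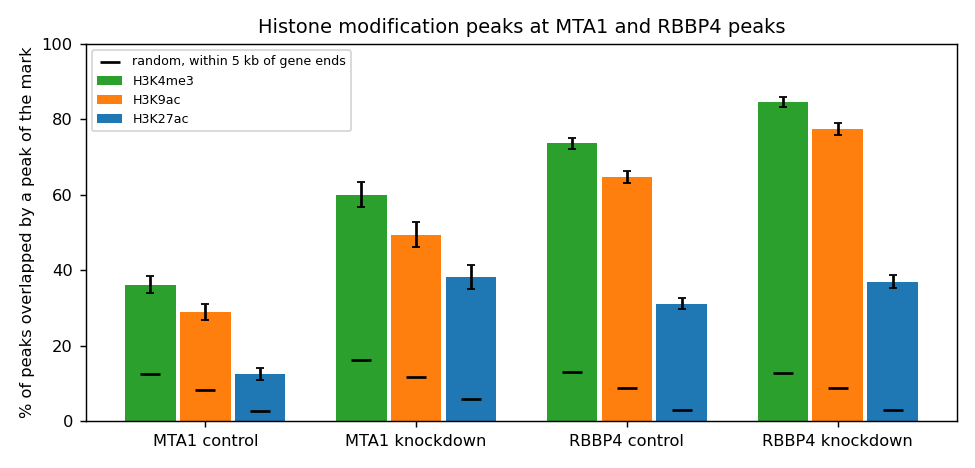
Share of MTA1 and RBBP4 peaks (y axis, percent) overlapped by a peak of H3K4me3 (green), H3K9ac (orange) or H3K27ac (blue) in unmodified cells, for the control and knockdown lists (x axis); error bars are exact 95% binomial intervals and black dashes the mean of 1000 random placements within 5 kb of gene ends. H3K4me3 overlapped 73.7% of RBBP4 control peaks against 12.9% of the random placements.

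The sequential ChIP, which asks for H3.3 and RBBP4 on the same chromatin fragments, gave 6 peaks, each inside or within 268 bp of an end of a gene. In order of the authors' fold enrichment they were beside H2afx (chr9:44142335-44142595, 10.7-fold), which encodes the histone variant phosphorylated at DNA breaks and lies close to Dpagt1, and at Kif2c (chr4:116854887-116855221, 10.2-fold), a kinesin of the centromere. Next came Mcph1 (chr8:18595145-18595377, 8.49-fold), a regulator of chromosome condensation, Cdc25c (chr18:34911403-34911629, 8.47-fold), the phosphatase that starts mitosis, Aurkb (chr11:68859169-68859389, 5.56-fold), a mitotic kinase, and Fam64a (chr11:71855503-71855735, 4.59-fold), a gene expressed in dividing cells. Their −log10 q ran from 11.3 at H2afx to 2.42 at Fam64a. Each of the 6 was overlapped by an RBBP4 peak in control cells, by one in knockdown cells and by an H3K4me3 peak. H3K9ac overlapped 4 and H3K27ac 1 of them. MTA1 peaks overlapped 0 in either condition, which with 6 peaks allows a share of up to 45.9% (exact 95% bound). In unmodified cells, however, the region that holds the Kif2c peak (chr4:116854251-116855614) had a peak of all 6 subunits, MTA1 included. The treatment library had 20.4 M tags and the IgG control 4.92 M, and there was 1 library of each.

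Regions with peaks of several NuRD subunits were more often H3.3 regions, but they were also longer. Of 52607 regions without a subunit peak 43.7% had an H3.3 peak in both replicates, against 50.3% of regions with 1 subunit and 78.0% of the 12063 with 2 or more. The median length rose from 768 bp without a subunit peak to 2486 bp with all 6. Among the longest 25% of regions (1370 to 18191 bp) the shares were 81.5% without and 97.6% with 2 or more subunits, and among regions of 840 to 1370 bp 62.1% and 76.9%. Among regions of 550 to 840 bp they were 33.9% (33.2 to 34.6) and 31.5% (28.9 to 34.2), within counting error. With 3 or more subunits the share there was 24.0% (19.7 to 28.8), below that without a subunit. In the shortest 25% (75 to 550 bp) the direction turned, with 10.6% without and 1.58% with 2 or more. Regions with 1 subunit had 1.46%, 46.4%, 83.5% and 96.7% from the shortest to the longest class, above those with 2 or more in both middle classes, so within a length class the share did not rise steadily with subunit number. A region without a subunit peak has an H3.3 peak in at least 1 replicate by construction, which raises its share. RBBP4 had a peak in 25717 regions (31.0%), HDAC2 in 11095, HDAC1 in 5238, MTA1 in 3017, MBD2/3 in 2629 and CHD4 in 2017, and 28.2% to 42.8% of these lay at annotated promoters.

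**Figure D5:**
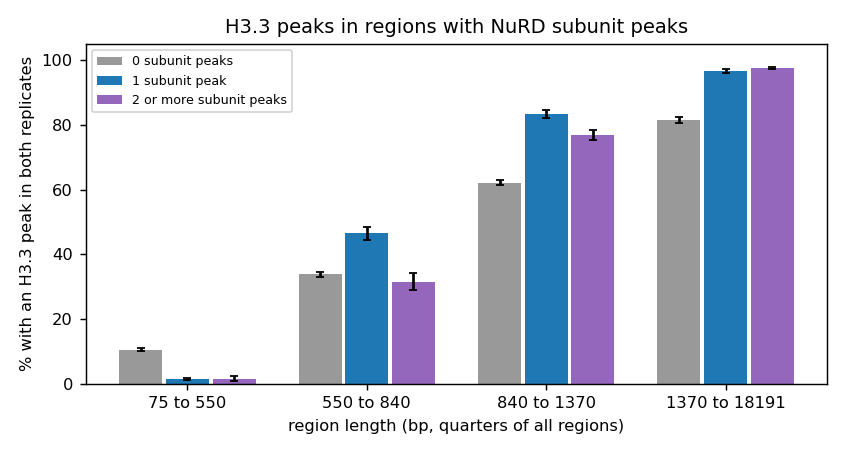
Share of regions with an H3.3 peak in both HA-H3.3 replicates (y axis, percent) by region length (x axis, bp, each class 25% of all regions) for regions with 0 (grey), 1 (blue) or 2 or more (purple) NuRD subunit peaks; error bars are exact 95% binomial intervals. In the longest regions the share is 97.6% with 2 or more subunits against 81.5% with none, and in the shortest 1.58% against 10.6%.

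The level of H3.3 correlated weakly with that of each subunit across the 82893 regions: rho was 0.205 for RBBP4, 0.193 for HDAC2, 0.170 for HDAC1, 0.150 for MTA1, 0.141 for CHD4 and 0.101 for MBD2/3, with a median of 0.160. Regions are not replicates, and no p-value is attached. Each region was listed because it holds an H3.3 or a subunit peak, so one without the first holds the second, which can lower rho. H3.3 was measured in arrested cells given doxycycline, and the subunits in unmodified cells. The HA-H3.3 replicates correlated with r = 0.684 and rho = 0.631, and the median over subunits was 0.0903 without replicate 1 and 0.204 without replicate 2. In the shortest 25% of regions the median rho was −0.234 and in the longest 0.372, and at annotated promoters it was 0.0423. The subunits correlated with each other at 0.438 to 0.686 over 15 pairs. The highest H3.3 level lay at Rn45s (chr17:39979842-39985867, annotated as 5'UTR, 66.3 and 60.1 RPKM), followed by the intergenic sites chr2:98506340-98507546 and chr2:98502333-98503208. The same 3 regions had the highest level of each of the 6 subunits. Levels were not divided by input, so signal that all libraries share at these regions cannot be told apart from binding. All 6 subunits had a peak in 108 regions.

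With all clones, genes with an RBBP4 peak at an end did not pass the test for a different response to H3.3 knockdown. The 1786 genes with an RBBP4 control peak had a median log2 difference of −0.15 against −0.09 in other genes (camera in limma, adjusted p = 0.438), and the 428 with an MTA1 peak had −0.13 against −0.10 (adjusted p = 0.466). The 920 genes whose RBBP4 peak was overlapped in knockdown had a median of −0.19 (adjusted p = 0.280), and the 866 whose peak was not had −0.11 (adjusted p = 0.843). Lost against kept differed by 0.08 (camera adjusted p = 0.367); a permutation of gene labels gave p = 0.00013, but genes are not replicates and that test ignores the spread between clones. For MTA1 the 317 genes with a lost and the 111 with a kept peak differed by 0.03 in the median with camera pointing the other way (adjusted p = 0.932). The median of the genes with a kept RBBP4 peak minus that of other genes was −0.10; it was −0.17 without control clone 2, where the set passed the camera threshold (adjusted p = 0.0342), and −0.05 without control clone 1 (adjusted p = 0.930) or knockdown clone 1 (0.542). With all clones and an estimated correlation the adjusted p of this set was 0.698, as it was for lost against kept RBBP4 peaks and for all genes with an RBBP4 or MTA1 peak. The difference of lost against kept RBBP4 peaks was 0.13 without control clone 2 or knockdown clone 3, 0.04 without control clone 1 and 0.02 without knockdown clone 1.

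Among genes with a region at an end, H3K9ac and H3K4me3 followed expression in control cells more closely than H3.3 did. This did not hold among those with a mean FPKM of at least 1. Every region holds an H3.3 or subunit peak, so genes without one were left out. The order of H3.3 against the marks may depend on that selection. Over 13962 genes rho with control expression was 0.378 for H3K9ac, 0.320 for H3K4me3, 0.190 for H3K27ac, 0.187 for HDAC1, 0.160 for HDAC2, 0.158 for H3.3, 0.118 for CHD4, 0.113 for MBD2/3, 0.101 for MTA1 and 0.0998 for RBBP4. The mean H3.3 level, as log2(RPKM + 1), was 1.96, 2.08, 2.11 and 2.19 from the lowest to the highest of 4 equal groups by expression, and that of H3K4me3 was 1.62, 3.24, 3.39 and 3.17. Among genes with a mean FPKM of at least 1, rho was 0.0886 for H3.3, 0.0766 for H3K9ac, 0.0375 for H3K27ac and 0.00244 for MBD2/3. It was negative for H3K4me3 (−0.0574), RBBP4 (−0.110), HDAC2 (−0.0598), MTA1 (−0.0185), HDAC1 (−0.0176) and CHD4 (−0.00808). At gene ends with an H3K4me3 peak rho for H3K9ac (0.150) stayed above that for H3.3 (0.0936), and that for H3K4me3 (0.0341) did not. These are correlations across genes, which are not replicates.

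For none of the 10 levels at gene ends did the genes of highest level pass the test for a different response to knockdown. Over 10734 genes rho with the log2 difference was 0.0483 for H3.3 and −0.0463 for RBBP4, the values farthest from 0. The 2683 genes in the top 25% of H3.3 level had a median of −0.07 against −0.11 in other genes (camera in limma), and the adjusted p was 0.964 for every level. For H3.3, rho with the difference of each knockdown clone from the controls was 0.0322, 0.0459 and 0.0471, and with the difference of control clone 1 from control clone 2 it was −0.00402. For RBBP4 the same values were −0.0889, 0.0228 and 0.000920, and 0.0824 between the control clones; its rho with the log2 difference was −0.00763 without control clone 1 and turned to 0.00877 without knockdown clone 1. For H3K4me3 they were −0.0888, 0.0685 and 0.0360, and 0.127 between the control clones.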

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

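The tests on region length, on gene ends with an H3K4me3 peak, on short RNA genes and on 10 or more estimated fragments were chosen after the results were seen. Of the alternatives to the leading results 65 left them on the same side, 13 moved a value, 1 reversed one, 5 raised and 6 lowered a count or call; for the other results the numbers were 923, 36, 14, 28 and 32. Among 35 named genes in 17 settings 537 of 572 values stayed on their side of the threshold, and 0 reversed among values with a call. A turn of sign in a gene without a call was counted as the same side. Over fits with 1 clone left out, the log2 difference ran from −0.617 to 0.255 for Mbd3 and from −0.149 to 0.359 for Hdac1. The sign also turned for Mta2, Gatad2b, Hdac2 and Rbbp7. Where no cause is given, the cause was not tested.

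Limma called 4 genes, 12 with array weights, 0 without short RNA genes, 0 with at least 10 estimated fragments (1228 at an unadjusted p under 0.05) and 5 to 36 with 1 clone left out, where a lone control is assumed to vary like the other clones. Of the 21 lists 5 were called, 3 to 5 with 1 clone left out and 0 with the estimated correlation; under quantile normalization ribosomal genes reversed (a mean difference to other genes of −0.0352). Clone numbers did not pair the samples (r = −0.250 and −0.0952 for the same number). The replicate block uses clones 1 and 2 alone: limma called 5 genes in them without the block and 0 with it (505 at an unadjusted p under 0.05). It called the same 5 lists with and without the block, with collagens (FDR 0.0111, and 0.00612 without it) in place of sterol genes (0.280 and 0.431), a swap that goes with leaving out knockdown clone 3. For peak genes the block was run on the peak, lost and kept sets. No paired analysis was possible for the HA-H3.3 replicates because the input values they share numbers with were not used here.

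Overlap of MTA1 control peaks was 18.1% within 1 kb, 38.7% at a score of 100 or more in both lists and 26.1% with equal numbers of peaks; for RBBP4 it was 46.5%, 45.9% and 39.3%, and 20.6% when 50% of the peak had to overlap. The fold of H3K4me3 at RBBP4 peaks over random placement, 27.1, was 5.72 near gene ends, where such peaks are common. The median rho of H3.3 with subunits was 0.0423 at promoters, 0.0903 to 0.204 with 1 replicate left out, and −0.234, 0.0655 and 0.372 in length classes 1, 2 and 4 of 4, from short to long. The share of H3.3 regions with 2 or more subunits minus that with none was −9.01 and −2.40 percentage points in length classes 1 and 2.

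The rank correlation with expression in genes of FPKM 1 or more was 0.0886 for H3.3, −0.00808 for CHD4, −0.0176 for HDAC1, −0.0598 for HDAC2, −0.0185 for MTA1, −0.110 for RBBP4 and −0.0574 for H3K4me3. At gene ends with an H3K4me3 peak it was 0.0936 for H3.3, 0.150 for H3K9ac, 0.0530 for H3K27ac, 0.0341 for H3K4me3, 0.00787 for HDAC1, −0.0124 for CHD4, −0.0350 for HDAC2, −0.000802 for MBD2/3, −0.0188 for MTA1 and −0.0972 for RBBP4. Not run, because no fold or input value was at hand, were a fold of 5 in peak and mark lists, ratios and levels over input and the pairing of inputs. Depth limits the region values most for HDAC2 and MBD2/3, with a median of 7 reads per region.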

Other observations

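Of the tests in this part, those on gene lists with RBBP4 peaks, on peak scores, on peak regions of unmodified cells, on H3K4me3 genes and on short RNA genes were chosen after the results were seen; the others were set down before their results were seen.

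RBBP4 sat at the ends of genes of particular groups in control cells. Of 16 expressed axon guidance and adhesion genes 13 (81.3%) had an RBBP4 peak within 2 kb of an end, against 15.1% of other genes (Fisher's exact test, adjusted p = 1.7e-07 over 21 lists). They included the ligands Slit2, Slit3, Sema3c and Sema5a, the receptors Nrp1, Nrp2, Plxna2, Epha4 and Ephb2 and the cadherin Cdh2, and 10 of the 13 had a peak in knockdown cells too. Of 22 immediate early genes 11 (50%) had one, among them Jun, Junb, Fosb, Fosl2, Egr3, Klf2, Klf4 and the phosphatase genes Dusp1, Dusp5 and Dusp6 (exact adjusted p = 0.00144), and 7 of the 11 had one in knockdown cells too. Of 15 interferon-stimulated genes and of 15 p53 targets 0 had one (Fisher's exact test, unadjusted p = 0.149 and adjusted p = 0.430 for each list), and of 31 ribosomal protein genes 2. Genes are not replicates, and each peak list is 1 library.

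The low share of control peaks found again in knockdown cells was weighed against technical explanations. Peaks near the calling threshold cannot be told apart from a partial loss of binding that spares the highest peaks: that 86.0% (82.4 to 89.1) of RBBP4 and 83.3% (71.5 to 91.7) of MTA1 control peaks with a score of 200 or more were overlapped restates the observation. Spread between experiments with the same antibody is a candidate explanation: only 24.8% (23.4 to 26.3) of RBBP4 control peaks, and 4.40% (3.48 to 5.49) of MTA1 control peaks, lay in as many of the highest regions of unmodified cells, fewer than lay in knockdown peaks. Those highest regions were ranked by read level and not by peak score. These shares are thus unlike an overlap of peaks and cannot decide the question. Against the 25717 regions with an RBBP4 peak in unmodified cells, 67.5% of control and 80.1% of knockdown peaks lay inside. That is above the 33.9% of control peaks found again in knockdown, but the regions far outnumber the 2919 knockdown peaks. Against the 3017 regions with an MTA1 peak the shares were 7.05% and 16.8%, where the MTA1 knockdown peaks were wider than the control ones. Loss of binding through H3.3 depletion stays open and was not tested, since each condition has 1 library.

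The number of MTA1 peaks, 904 in knockdown against 1703 in control cells, was not brought level by joining control peaks within 861.5 bp, the median knockdown peak width, which left 1518 control peaks, a ratio of 1.68.

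The fall of the cell cycle list in the knockdown clones was weighed next. By the bound set beforehand, the values went against a fall that grows with the strength of depletion. The median of clone 3, with the least H3f3a, lay 1.07 above that of clone 1, with the most. That result rests on clone 1, which stood apart over all genes, a limit raised only after the values were seen. Clones 2 (−0.28) and 3 (−0.54) lie in the order of depletion, but clone 2 lies within the control range, so their order decides nothing. With so few clones, strength of depletion cannot be told apart from clone differences. Whether clone 1 alone sets the list cannot be told apart from a shared fall: without it camera in limma gave an FDR of 0.0435 (0.00622 before adjustment), but the mean difference to other genes went from −0.69 to −0.30, clone 2 lies within the control range of −0.32 to 0.32 and without control clone 1 the call ended (FDR 0.251). A difference in growth between clones and an effect of H3.3 depletion both stay open as untested.

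The 4 genes past the test were all short RNA genes, against 363 of the 11728 tested (Fisher's exact p = 9.03e-07), which restates the observation and decides nothing about its origin. With at most 2 estimated fragments per library, sampling of few fragments in very short transcripts cannot be told apart from a change in these RNAs with H3.3 depletion.

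The sequential ChIP peaks at cell division genes led to the hypothesis that RBBP4 sits at cell cycle genes apart from MTA1. Of the 27 genes of the cell cycle list 11 (40.7%) had an RBBP4 control peak, against 15.2% of other genes (Fisher's exact p = 0.00121, adjusted p = 0.00849 over the 21 lists), and 0 had an MTA1 control peak, against 3.66% (exact p = 0.625, a test with little power at that share). The 11 were Aurka, Aurkb, Bub1, Ccna2, Ccne2, Cdc20, Cdc6, Cdk1, Chaf1a, Rrm2 and Top2a. Among genes with an H3K4me3 peak the RBBP4 excess gave an exact p = 0.00248, and in knockdown cells 17 of the 27 had an RBBP4 peak (exact p = 4.84e-08). The RBBP4 values go with the hypothesis, while the MTA1 side could come from the small number of MTA1 peaks. The region at Kif2c, a sequential ChIP gene outside the list, also had an MTA1 peak in unmodified cells.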
